A study of Hordeum vulgare with 12 samples.

How the data were processed

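The deposited files held the scanner output of 12 one-colour (Cy3) Agilent barley arrays, 1 per biological replicate, with 45220 spots each, and a value table of the whole series. Per the labels, cells were laser-microdissected from dried cryosections, each replicate was pooled from sections of several grains, and RNA passed through repeated rounds of linear amplification before labelling. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed signal is an intensity on a linear scale that Feature Extraction had background-subtracted and spatially detrended within each array, and it was not normalized between arrays. The deposited value table holds log2 values; set against the scanner files its columns had the rank order of the median spot intensity (Spearman rho of 1 on every array), and their medians lay from 8.818 to 8.820, as after quantile normalization. Its scale and centring were inferred from this comparison alone.

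Control spots and spots with an outlier flag were left out, spots of a probe were averaged, and the log2 of the processed intensity was reduced by the array's 75th percentile of it. This normalized log2 signal is the unit of all levels in the text, and it compares a probe between arrays, not different probes. No spot was saturated. Outlier flags removed 0.208% to 14.6% of spots per array, most on 5 DAF replicate 2. Probes were tested where they were well above background on all 3 arrays of at least 1 stage (19173 probes), less 35 that flagged spots left with under 2 values in a stage. A probe below background on every array of a stage has only a bound there, and its fold is given as "at least", from the mean of the brighter stage against the lowest signal well above background on each array of the dimmer stage or the probe's own value if higher. Such a bound holds for this background treatment and scaling alone.

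Stages were compared with limma 3.58.1 in R 4.3.3, in 1 fit of 12 arrays with a mean per stage, no covariates and the default empirical Bayes variance, two-sided, with Benjamini-Hochberg adjustment over the 19138 probes and a threshold of 0.05. The comparisons were 7 against 5, 10 against 7, 12 against 10 and 12 against 5 DAF and an F test over the stages. Other tools were statmod 1.5.0, version 1.17.8 of data.table, and matplotlib 3.10.9 under Python 3.11.15 for the plots. The labels give separate biological replicates. Stages, tests, gene lists and the rule for named genes were fixed before the data were examined.

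Named genes were, in each comparison, up to 6 with the largest increase and 6 with the largest decrease among probes past the threshold with an informative description, an absolute log2 fold change of at least 1 and no overlap between the values of the stages, and 2 members with the smallest adjusted p from each of the 8 lists with the smallest camera p. Gene names are those of the array's design and are old. Of 43603 probes, 6021 had a description naming a protein or function, 20227 were described as unknown and 17355 only by a clone, locus or predicted protein. A RefSeq gene table of the MorexV3 assembly matched the identifiers of 3 probes, so names were kept as the files give them and no coordinates are given. Lists were patterns on these descriptions. Pattern hits whose description showed another function were removed by reading the descriptions, without sight of their signals, and a run with every hit kept is among the alternatives. The heat shock list was fixed as a check on sample quality. The list for transfer cell markers kept 0 probes and was void. The other 34 lists each had at least 5 measured genes, with 1 probe per gene, and were tested in 4 comparisons (136 tests) with limma's camera at a preset correlation of 0.01, adjusted over the 136. Of 26 calls, 0 held with an estimated correlation. fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 45.

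The fit and the list test were tested on simulated arrays with the measured means and variances and 200 changed probes among 19138. For 7 against 5 DAF the share of changed probes recovered was 4% at a log2 change of 1, 62% at 2, 80% at 3 and 96% at 4. For 12 against 10 DAF it was 14%, 74%, 86% and 94% at those sizes. All simulated arrays had the same mean and spread for a probe, so these comparisons differ by little but the random draw. Their difference says nothing about the stages. For 7 against 5 DAF the real arrays had 35.3% of probes called, far more than were changed here, so the shares do not carry over to that comparison. The list test called a list of shifted genes (camera adjusted p = 1.8e-20 for 7 against 5 DAF) and 0 of 34 other lists. Probes were drawn independently of each other, whereas the estimated correlation within the real histone list was 0.555. The list test was therefore not tried at the correlations of the real lists.

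Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the deposited value table, no filter and a stricter filter on dim probes, a replicate block, scan date as a block, slide as a random block (each of the 9 slides holds 1 stage), a variance trend with robust fitting, array weights, only the 2 stages compared, a fold minimum and leaving out each array. The 12 arrays carried 3 scan dates, 10 arrays on 1 date and 5 DAF replicate 3 and 7 DAF replicate 3 each on a date of its own, so the date block leaves those 2 arrays without weight in the comparisons. Their median local background was 29.5 and 56, against 387 to 1087 on the other arrays. Per the file headers, 7 DAF replicate 3 was also read on another scanner than all other arrays.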

Results

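Endosperm transfer cells are the cell layer of the young barley grain that faces the maternal nucellar projection and takes up assimilates for the endosperm. They were isolated by laser from frozen sections of grains of the cultivar Barke at 4 stages. These were 5, 7, 10 and 12 DAF, where DAF stands for days after flowering. Each stage had 3 biological replicates, each collected from sections of 3 grains, and each replicate was hybridised to 1 one-colour Agilent array, which gave 12 arrays. Of 43603 probes, 19138 were well above background on all 3 arrays of at least 1 stage and were tested, and they carried 16014 gene names. Only 3649 of the tested probes had a description that names a protein or function, so the named genes and gene lists speak for that part of the array. The share of probes well above background per array was 35.7% to 38.1% at 12 DAF and 40.4% to 53.5% on the other arrays, apart from 7 DAF replicate 3 with 79.3%, the only array read on another scanner. Precision was limited by the 3 arrays per stage. Folds of dim genes also depend on the background treatment. With normexp 54 of the 88 named results past the test had a fold smaller by over 1.5 times and 13 of 15 printed bounds were not reached, and with the deposited values 44 and 4.

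Stage was the main source of variation. The first principal component held 48.5% of the variance and placed 5 DAF apart from 10 and 12 DAF, and the second held 24.1% and placed 7 DAF apart. Across the 4 stages, limma's F test called 10692 probes, of which 3693 had their highest mean at 5 DAF, 2227 at 7 DAF, 2708 at 10 DAF and 2064 at 12 DAF. Among list members past the F test, with signals scaled to the 75th percentile, 97 of 106 histone genes and 53 of 59 genes of cytosolic ribosomal proteins were highest at 5 DAF. For transcription factors, 28 of 56 were highest at 12 DAF, and for photosynthesis genes 11 of 16 were highest at 10 DAF. With scan date as a block the F test called 10876 probes, and with slide as a random block 8147.

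**Figure D1:**
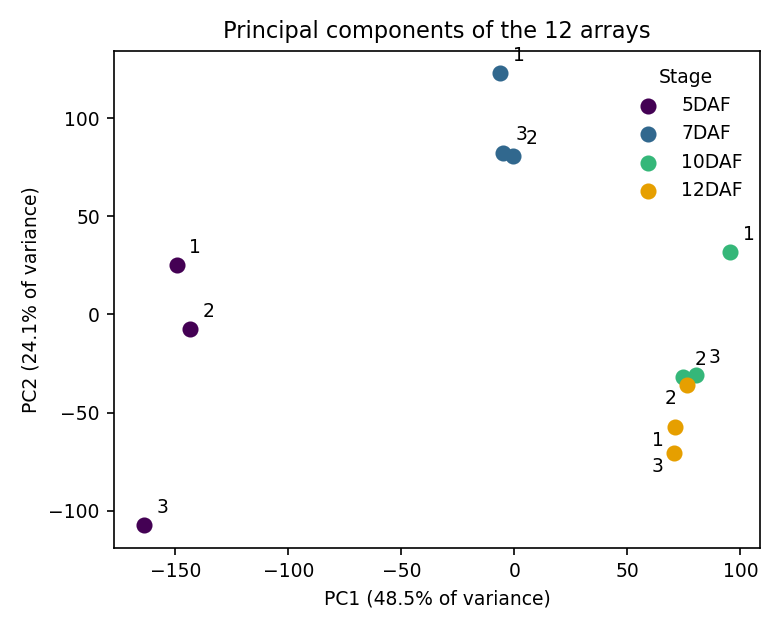
First and second principal components of the 12 arrays, computed from 18393 tested probes with complete values, with the share of variance on each axis. Points are arrays coloured by stage and numbered by replicate, and the 5 and 7 DAF arrays lie apart from the rest while 10 DAF replicates 2 and 3 lie next to 12 DAF replicate 2.

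**Figure D2:**
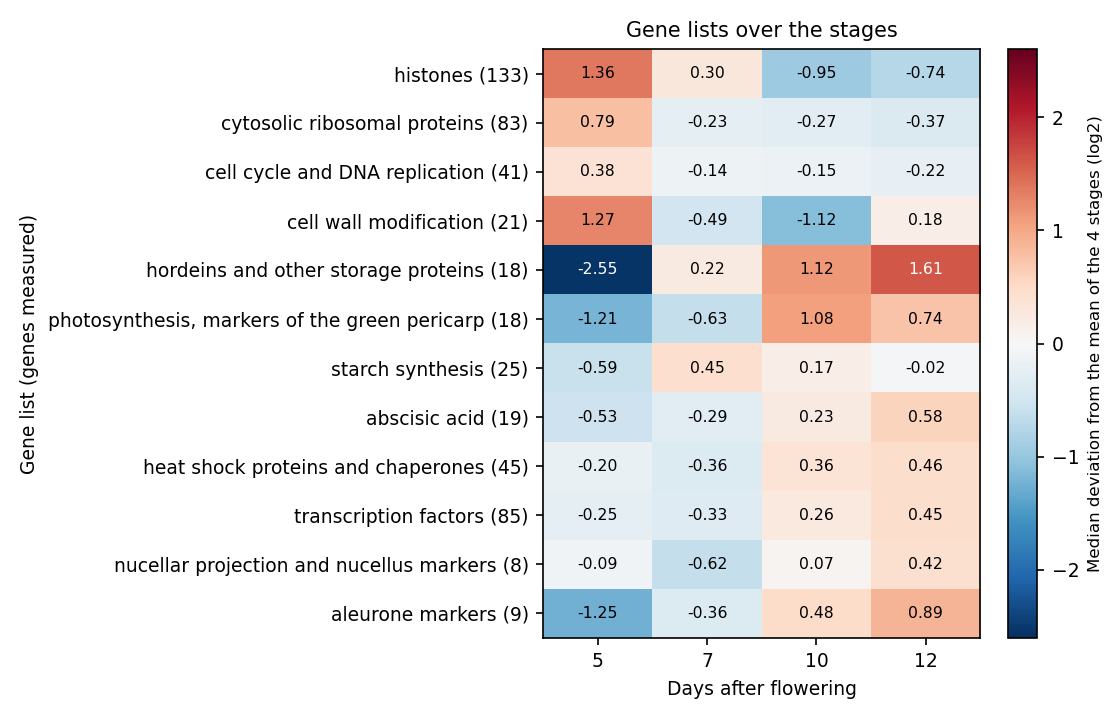
Stage profiles of 12 gene lists, with days after flowering on the horizontal axis and the number of measured genes beside each list. Each cell gives the median over the list's genes of the stage mean minus the mean of the 4 stages (log2), which for histones went from 1.36 at 5 DAF to -0.95 at 10 DAF and for storage proteins from -2.55 at 5 DAF to 1.61 at 12 DAF, while the medians of the heat shock and transcription factor lists fell over the span under median scaling, which lowered all probes alike, and their tests stayed upward.

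The step from 5 to 7 DAF asks which transcripts change as the transfer cells begin to differentiate. Hordoindoline-a (TA32310_4513), a grain hardness protein, rose 180-fold from -5.75 ± 2.44 to 1.74 ± 0.16 (normalized log2 signal, mean ± SD, n = 3 each; limma adjusted p = 0.00019), and it was well above background on 1 of 3 arrays at 5 DAF. This fold was 67.6 without 5 DAF replicate 3 and 296 and 289 without replicates 1 and 2, and its log2 value was 5.29 with normexp. Hordoindoline-B1 (TA31077_4513) rose 87.6-fold, with a log2 fold change of 6.45 ± 0.37 (SE). Of 18 measured genes of hordeins and other storage proteins, a list fixed among the markers of tissues that a sample could hold, 10 rose and 1 fell, the same numbers when adjusted over the list alone (limma camera, adjusted p = 3.9e-05; adjusted p = 0.0858 with an estimated correlation). Whether this rise came from the transfer cells or from RNA of neighbouring tissue was not tested. Trypsin inhibitor CMe (LOC548239), counted with this list, rose 6.72-fold.

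Of 25 starch synthesis genes, 12 rose and none fell, and 14 rose when adjusted over the list alone (camera adjusted p = 0.000288; adjusted p = 0.555 with an estimated correlation). The median log2 fold change of the list was 0.972, but 0.063 under median scaling, where its list call held. Glucose-1-phosphate adenylyltransferase (TA39734_4513), which makes the ADP-glucose used for starch, rose 4.45-fold to 4.17 ± 0.02 (SD, n = 3). The plastidial ADP-glucose transporter (TA36467_4513) rose 5.04-fold. A histidine-containing phosphotransfer protein (TA50711_4513), an intermediate of two-component signalling, rose 6.12-fold from 0.79 ± 0.14 to 3.40 ± 0.20 (SD, n = 3), while cytokinin dehydrogenase (LOC548127), which degrades cytokinins, fell 7.68-fold. The two-component and cytokinin list of 6 genes did not pass the test (camera adjusted p = 0.133). The call of cytokinin dehydrogenase ended with slide as a random block (adjusted p = 0.054) and without 5 DAF replicate 1 or 2 or 7 DAF replicate 1 (adjusted p = 0.051, 0.055 and 0.069), and its fold was 13.1 without 5 DAF replicate 3 and 4.82 and 11.7 without 7 DAF replicates 1 and 2. The light-harvesting protein Lhcp2.3 (TA47820_4513) rose 12.3-fold and a light-harvesting complex I protein (LHC Ib-20) 2.78-fold, the latter not under median scaling (adjusted p = 0.36) or with the deposited values (adjusted p = 0.08). The photosynthesis list as a whole did not pass (camera adjusted p = 0.0861).

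Of 83 genes of cytosolic ribosomal proteins, 46 fell, 1 rose and 36 did not pass. Adjusted over the list alone, 50 fell and 1 rose (median log2 fold change -1.03; camera adjusted p = 2.67e-10; adjusted p = 0.693 with an estimated correlation). Ribosomal protein S10 (TA28334_4513) fell 2.73-fold from 3.12 ± 0.08 to 1.67 ± 0.16 (SD, n = 3) and the 60S protein L6 (BI960355) 7.46-fold, which was well above background on 1 of 2 arrays with a value at 7 DAF. Of 133 histone genes, 56 fell and none rose. Adjusted over the list alone, 60 fell (camera adjusted p = 2.74e-09; adjusted p = 0.832 with an estimated correlation), among them histone H2B.2 (TA29627_4513), 3.64-fold lower, and histone H2B.1 (TA29601_4513), 4.55-fold lower. Of 41 cell cycle and DNA replication genes, 20 fell and 5 rose. Adjusted over the list alone, 20 fell and 6 rose (camera adjusted p = 0.0203; adjusted p = 0.144 with an estimated correlation), a list call lost under median scaling (adjusted p = 0.059). A kinesin-related protein (TC175525), well above background on 1 of 3 arrays at 7 DAF, fell 24.9-fold and cyclin-D6-1 (TA49348_4513) fell 3.61-fold. Of 21 cell wall modification genes, 10 fell and 2 rose. Adjusted over the list alone, 11 fell and 2 rose (camera adjusted p = 0.000473; adjusted p = 0.299 with an estimated correlation), including a beta-glucanase (TA51976_4513), 10.3-fold lower and well above background on 2 of 3 arrays at 7 DAF, and an enzyme described as 3-glucanase (TA45124_4513), 6.3-fold lower.

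Among the steepest single changes, an 18 kDa heat shock protein (X64561) rose 87.1-fold, class III peroxidase 135 (TA42544_4513) rose 84.9-fold and the 27K protein (TA29367_4513) rose 91.3-fold. A transcript whose old description names a flagellar protein, FliL (TA34846_4513), rose 99.7-fold, and this description was taken as the files give it. FliL and the 27K protein were well above background on 2 of 3 arrays at 5 DAF. Without 5 DAF replicate 2 or 3 the fold was 132 or 51.9 for the heat shock protein and 62.2 or 171 for FliL. Formate dehydrogenase (TA31856_4513) fell 182-fold from 2.99 ± 0.99 to -4.52 ± 0.83 (SD, n = 3). Nitrate reductase (BM374841) fell 90.5-fold, an enoyl-CoA hydratase (TA37100_4513) 151-fold, a cytochrome P450 (TA33003_4513) 66.5-fold and the beta-D-glucan exohydrolase ExoI (AF102868), a wall glucan hydrolase, 68.4-fold. At 7 DAF the dehydrogenase, the reductase and the hydratase were well above background on 1 of 3 arrays each and the cytochrome P450 on 1 of 2 with a value, so that these fold values rest partly on readings near background. Nitrate reductase was 0.40 ± 1.76 (SD, n = 3) at 5 DAF, and its fold was 44.9 without 5 DAF replicate 2. With normexp the log2 fold changes of these 4 were -5.82 for formate dehydrogenase, -4.52 for nitrate reductase, -4.64 for the hydratase and -3.99 for the cytochrome P450, against -7.51, -6.5, -7.24 and -6.06. Allantoin permease (TA35690_4513) was not well above background on any 7 DAF array and was at least 33.3-fold lower than at 5 DAF. This bound was 11.9 without 7 DAF replicate 3, whose lowest signal well above background lay far under that of the others, and 52.5 and 58.9 without replicates 1 and 2. With normexp its log2 fold change was -4.8, which is less than the bound. Jekyll (TA30547_4513) and nucellin (TA33203_4513), markers of the neighbouring nucellar tissue, had log2 fold changes of -4.47 and -5.23 (limma adjusted p = 0.013 and 0.0037), and 75 of the 3104 lower probes (2.42%, against 0.967% of all tested probes) varied within stages with the mean of that pair at r over 0.8 across arrays. This pair was chosen after its values were seen. Without 5 DAF replicate 3 the log2 fold changes were -5.54 and -5.99, without 7 DAF replicate 1 -3.75 and -4.61, where the call of jekyll ended (adjusted p = 0.053), and without 7 DAF replicate 2 -5.15 and -5.85. Without 5 DAF replicate 2 that of jekyll was -3.75.

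In all, 6763 probes differed between 7 and 5 DAF, 3659 higher and 3104 lower at 7 DAF, and the 3 values of each stage did not overlap for 52.0% of tested probes, where chance gives 10%. The count was 4814 with scan date as a block, which equals the value within the one date that holds several arrays, 4849 with slide as a random block, and 4447 without 7 DAF replicate 1. The higher against lower split depended on the scaling, with 15.8% of calls higher under median scaling against 54.1%.

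**Figure D3:**
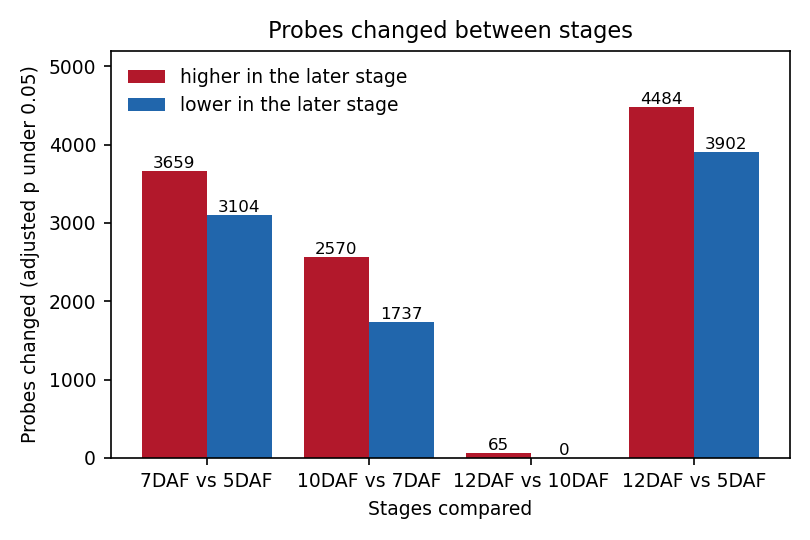
Number of probes past an adjusted p of 0.05 in each comparison of stages, with bars for probes higher and lower in the later stage. The bars for 12 against 10 DAF stand at 65 and 0, against 2570 and 1737 for 10 against 7 DAF.

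Between 7 and 10 DAF, an ABA-responsive protein (LOC548112) rose 38.9-fold from -0.96 ± 0.28 to 4.32 ± 0.82 (SD, n = 3; limma adjusted p = 0.00014), and 1 other probe of the gene had the same sign. Of 45 genes of heat shock proteins and chaperones, which assist protein folding and were fixed as a check on sample quality, 19 rose and none fell. Adjusted over the list alone, 22 rose and 1 fell (camera adjusted p = 0.000233; adjusted p = 0.343 with an estimated correlation). Whether this rise came from the quality of the samples or from their stage was not tested. Small heat shock proteins (TA32594_4513, TA32595_4513 and TA32593_4513) rose 59.8-fold, 15.5-fold and 7.38-fold, and a DnaK chaperone (TA46814_4513) rose 30-fold. The TA32594_4513 transcript was well above background on 2 of 3 arrays at 7 DAF. The abscisic acid list of 19 genes had 4 higher and none lower and did not pass as a list (camera adjusted p = 0.075), with a protein phosphatase 2C (TA44215_4513) 2.48-fold higher, though not without 7 DAF replicate 1 (adjusted p = 0.06) or with no filter on dim probes (adjusted p = 0.077).

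Of 133 histone genes, 67 fell and 3 rose in this step. When adjusted over the list alone, 85 fell and 7 rose (median log2 fold change -1.32; camera adjusted p = 9.17e-15; adjusted p = 0.693 with an estimated correlation). Histone H2A.1 (TA30084_4513) fell 8.23-fold from 2.65 ± 0.11 to -0.39 ± 0.52 (SD, n = 3) and protein H2A.6 (TC191293) fell 9.43-fold. Of 85 transcription factor genes, 25 rose and 3 fell. When adjusted over the list alone, 31 rose and 3 fell (camera adjusted p = 0.00423; adjusted p = 0.59 with an estimated correlation). A Myb-like protein of the SHAQKYF class (TA55313_4513) rose 15.4-fold, a Myb-related protein (TA41718_4513) 11-fold and a homeobox protein (TA52658_4513), well above background on 1 of 3 arrays at 7 DAF, 29.2-fold (44.9-fold without 7 DAF replicate 3).

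Of 18 photosynthesis genes, fixed as markers of the green pericarp, 11 rose and 1 fell. When adjusted over the list alone, 13 rose and 2 fell (median log2 fold change 1.67; camera adjusted p = 0.00897; adjusted p = 0.59 with an estimated correlation). The light-harvesting complex I protein LHC Ib-20 rose 4.6-fold, while Lhcp2.2 (TA48162_4513) was not well above background on any 10 DAF array and was at least 3.37-fold lower than at 7 DAF, a call lost with normexp (adjusted p = 0.065). Of 18 storage protein genes, 8 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.59 with an estimated correlation). Their list call was lost without 10 DAF replicate 3 (adjusted p = 0.16) under median scaling (adjusted p = 0.052) and with every pattern match kept (adjusted p = 0.11). Hordoindoline-B1 (BG367535) rose 2.96-fold to 4.35 ± 0.37 (SD, n = 3) and an amylase inhibitor-like protein (TA34545_4513) 2.84-fold, a call lost with slide as a random block (adjusted p = 0.097), with no filter on dim probes (adjusted p = 0.089), in a fit of these stages alone (adjusted p = 0.063) and without 7 DAF replicate 1 or 10 DAF replicate 2 or 3 (adjusted p = 0.094, 0.081 and 0.065). Among lipid metabolism genes, a patatin-like phospholipase (TA57126_4513) and a lipase-like protein (TA33122_4513) each rose 3.38-fold, in a list that did not pass (camera adjusted p = 0.0976). Of 9 aleurone markers, 1 rose and 4 were higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.173). The cold acclimation protein WCOR615 (TA33619_4513), well above background on 1 of 3 arrays at 7 DAF, rose 7.77-fold, a call lost with slide as a random block (adjusted p = 0.074), with no filter on dim probes (adjusted p = 0.087) and without any of the 6 arrays of these stages (adjusted p = 0.054 to 0.098).

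Single genes with steep changes included 12-oxophytodienoic acid reductase 1 (TA39729_4513), which rose 38.9-fold, and a probable molybdopterin-binding protein (TC183742), which rose 121-fold with a wide spread at 10 DAF (1.40 ± 3.0, SD, n = 3). A protein kinase-like protein (TA32130_4513) fell 28.4-fold, cyanate hydratase (TA44630_4513) 19-fold and the serine carboxypeptidase CP-MI (LOC548205) 20.5-fold. Fatty aldehyde dehydrogenase 1 (BQ294547) was at least 8.16-fold lower, a bound not reached with normexp (log2 fold change -2.65). An Adagio-like protein (BQ471978) fell 15.3-fold. At 7 DAF the reductase and the molybdopterin-binding protein, and at 10 DAF CP-MI and the Adagio-like protein, were well above background on 1 of 3 arrays each, and the kinase-like protein and cyanate hydratase on 2 of 3 at 10 DAF. Single arrays moved these folds. Without 10 DAF replicate 1 the fold was 45 for the molybdopterin-binding protein, 10.1 for the kinase-like protein and 11.9 for cyanate hydratase. Without 10 DAF replicate 2 it was 53.9 for the kinase-like protein and 9.79 for the Adagio-like protein. Without 10 DAF replicate 3 it was 357 for the molybdopterin-binding protein, 13.5 for CP-MI and 29.8 for the Adagio-like protein. With slide as a random block the calls of the protein kinase-like protein, CP-MI and the Adagio-like protein ended (adjusted p = 0.067, 0.074 and 0.085). They also ended for CP-MI and the Adagio-like protein with no filter on dim probes (adjusted p = 0.072 and 0.088), for CP-MI without any 7 DAF array or 10 DAF replicate 3 (adjusted p = 0.056 to 0.072) and for the Adagio-like protein without any array of these stages but 10 DAF replicate 3 (adjusted p = 0.065 to 0.097).

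In all, 4307 probes differed between 10 and 7 DAF, 2570 higher and 1737 lower at 10 DAF (4978 and 550 under median scaling), without overlap of the 3 values of each stage for 47.8% of tested probes (chance, 10%). The count fell to 1758 with slide as a random block and was 5240 with scan date as a block. It ranged from 1722 without 7 DAF replicate 1 to 7053 without 5 DAF replicate 3 and was 2075 without 7 DAF replicate 3, 2623 without 7 DAF replicate 2 and 2398 without 10 DAF replicate 2.

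**Figure D4:**
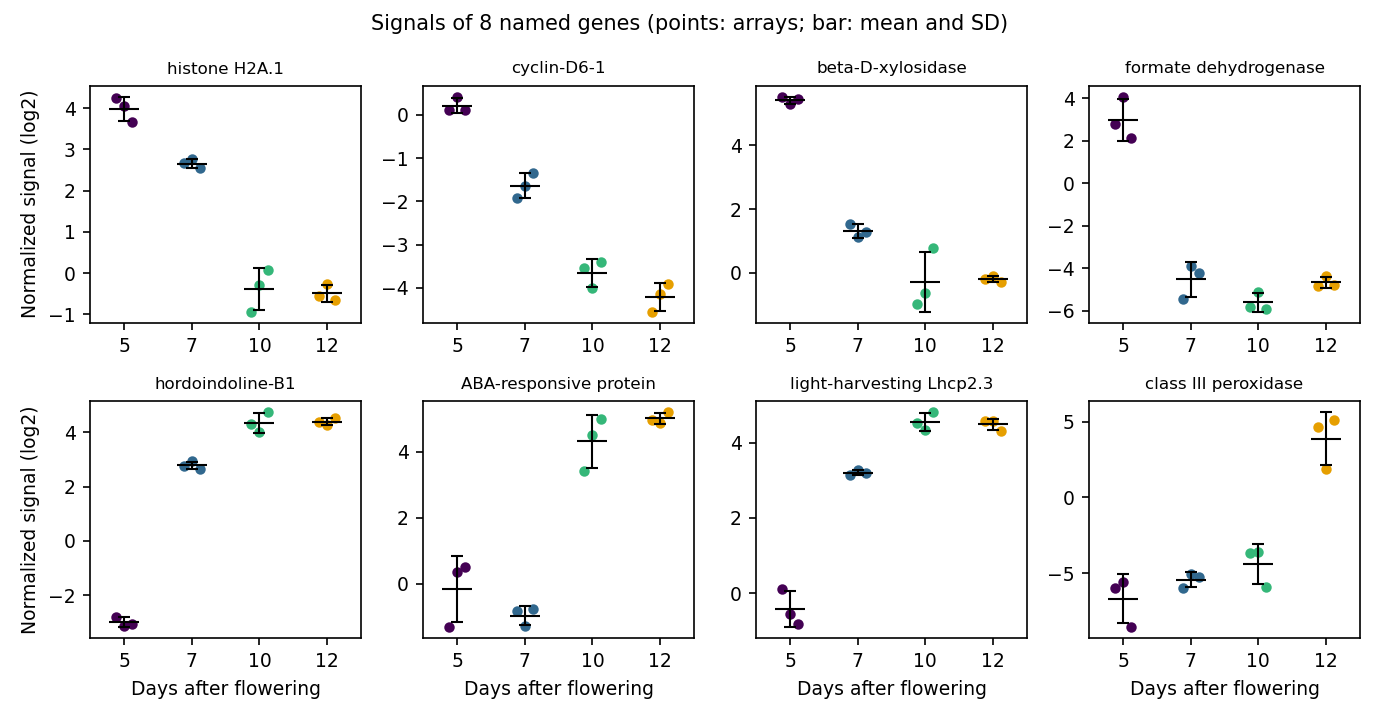
Normalized log2 signals of 8 named genes, by stage in days after flowering. Points are single arrays (n = 3 per stage), and bars are the mean and the SD. Histone H2A.1 went from 3.98 at 5 DAF to -0.49 at 12 DAF, and hordoindoline-B1 (BG367535) from -3.0 to 4.40.

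Between 10 and 12 DAF few probes passed the test, and every probe that did was higher at 12 DAF, although quantile normalization called 50 higher and 23 lower and array weights 545 and 88. Class III peroxidase 135 (TA36365_4513) rose 315-fold from -4.40 ± 1.30 to 3.89 ± 1.75 (SD, n = 3; limma adjusted p = 0.0061). The other named increases were a ripening-related protein (TA32904_4513), 194-fold, the serine carboxypeptidase CP-MI (LOC548205), a protease, 94.1-fold, a copper amine oxidase (TA45590_4513), 81.5-fold, and the C13 endopeptidase NP1 (AF082346), 41.4-fold. The rise of CP-MI was read on another probe than its fall from 7 to 10 DAF, so the 2 folds do not describe a single signal. The ABA-inducible protein PHV A1 (TA32029_4513) was at least 8.5-fold higher and the glutathione S-transferase GST 34 (TA35401_4513) at least 4.32-fold higher, since neither was well above background on any 10 DAF array. With normexp the log2 fold change of PHV A1 was 2.99, which is less than its bound. The peroxidase and the amine oxidase were well above background on 1 of 3 arrays at 10 DAF and the ripening-related protein on 2, so that their fold values rest partly on readings near background. The fold of the peroxidase was 187 without 10 DAF replicate 3 and 630 and 205 without 12 DAF replicates 2 and 3. That of the ripening-related protein was 112 and 297 without 10 DAF replicates 1 and 3 and 304 without 12 DAF replicate 2. For CP-MI it was 166 without 12 DAF replicate 2, and for the amine oxidase 45.5 and 180 without 10 DAF replicates 1 and 3. Without 12 DAF replicate 1 the calls ended for the peroxidase, the ripening-related protein, CP-MI and PHV A1 (adjusted p = 0.055 each), the amine oxidase (0.07) and GST 34 (0.14). Without 12 DAF replicate 3 they ended for the ripening-related protein (0.051), the amine oxidase (0.072) and GST 34 (0.13). GST 34 also lost its call without 10 DAF replicate 1 or 2 (0.065 and 0.081). A fit of these stages alone ended the calls of the peroxidase, the ripening-related protein, CP-MI, the amine oxidase and GST 34 (0.057 to 0.072), normexp those of PHV A1 (0.085) and GST 34 (0.12), and no filter on dim probes that of GST 34 (0.075). Slide as a random block ended the calls of GST 34 (0.12) and the ripening-related protein (0.066), whereas the call of NP1 held under all alternatives.

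Of the gene lists, cell wall modification shifted upward most clearly, though 0 of its 21 genes passed among all probes and 7 were higher when adjusted over the list alone (camera adjusted p = 3.14e-05; adjusted p = 0.144 with an estimated correlation). The size of this shift depended on the scaling. The median log2 fold change of the list was 0.647, and 0.692 with normexp, but 0.247 with quantile normalization, 0.208 with the deposited values and 0.014 under median scaling. Expansin-A23 (TA49015_4513), of a wall-loosening protein family and well above background on 1 of 3 arrays at 10 DAF, had a log2 fold change of 4.73 ± 0.82 (SE) with an adjusted p of 0.051. It ranged from 3.13 to 5.57 over the alternatives, of which 6 of 21 called it, and was 5.57 and 5.56 without 10 DAF replicate 3 and 12 DAF replicate 2 (adjusted p = 0.0098 and 0.0067). A pectinesterase (TA53527_4513) was at least 2.58-fold higher with an adjusted p of 0.13. Over the alternatives its log2 fold change ranged from 1.61 to 4.01, the highest without 12 DAF replicate 2 (adjusted p = 0.0065). Of 33 genes of proteases, programmed cell death and autophagy, 1 rose and 5 were higher when adjusted over the list alone (camera adjusted p = 0.00513; adjusted p = 0.262 with an estimated correlation). The papain-like proteinase pap-2 (AM941116) had a log2 fold change of 2.53 ± 0.52 (SE; adjusted p = 0.082), and 3.28 without 12 DAF replicate 2 (adjusted p = 0.0012). The protease list call was lost without 10 DAF replicate 3 (adjusted p = 0.079). The cell wall and protease lists varied within stages with the 65 called probes (r = 0.826 and 0.944 over the 12 arrays; adjusted permutation p = 0.026 each over 34 lists), and the 8 nucellar markers had r = 0.802 (adjusted permutation p = 0.058).

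Weaker list shifts, all upward, were found for abscisic acid genes (1 of 19 rose among all probes and adjusted over the list alone; camera adjusted p = 0.00897; adjusted p = 0.651 with an estimated correlation), redox and detoxification (3 of 63 rose, 5 adjusted over the list alone; camera adjusted p = 0.0171; adjusted p = 0.832 with an estimated correlation) and aquaporins (0 of 11 rose, 3 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.0899 with an estimated correlation). The aquaporins HvPIP1;4 and HvPIP2;1 had log2 fold changes of 4.42 ± 0.86 and 2.65 ± 0.63 (SE; adjusted p = 0.082 and 0.13), with HvPIP1;4 well above background on 2 of 3 arrays at 10 DAF. Without 12 DAF replicate 2 both passed, at 5.17 and 3.15 (adjusted p = 0.018 and 0.042), as HvPIP1;4 did without 10 DAF replicate 3, at 4.97 (adjusted p = 0.045). Over the alternatives HvPIP1;4 ranged from 2.94 to 5.17 and HvPIP2;1 from 1.98 to 3.15. Metal and ion transport passed narrowly with 0 of 23 genes past the test, also 0 adjusted over the list alone (camera adjusted p = 0.0493; adjusted p = 0.129 with an estimated correlation), and its adjusted p ranged from 0.018 to 0.32 over the alternatives. Its zinc transporter (BM816765) and potassium transporter (CK567278) had log2 fold changes of 0.94 ± 0.27 and -0.89 ± 0.26 (SE; adjusted p = 0.23 each). Under median scaling the median log2 fold change of the abscisic acid, redox, aquaporin, protease and metal transport lists turned negative, while the direction of their tests did not. Single arrays ended the calls of abscisic acid (without 7 DAF replicate 2 or 3, adjusted p = 0.06 and 0.054), redox (without 10 DAF replicate 1 or 3, 0.12 and 0.068) and aquaporins (without 5 DAF replicate 1 or 3 or 10 DAF replicate 3, 0.072, 0.097 and 0.068). Normexp ended all 3 (0.069, 0.08 and 0.06), and fry called none of them (0.37, 0.38 and 0.11) nor metal and ion transport (0.13). The histone and ethylene lists did not pass (camera adjusted p = 0.0514 and 0.0565).

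In all, 65 probes were higher and 0 lower at 12 DAF than at 10 DAF by limma, against 1745 at an unadjusted p under 0.05, and the 3 values of each stage did not overlap for 16.8% of tested probes (chance, 10%). The count was 67 with scan date as a block and 13 with slide as a random block, and ranged from 7 without 12 DAF replicate 1 to 330 without 12 DAF replicate 2, with 263 without 10 DAF replicate 3, 11 without 12 DAF replicate 3 and 19 without 10 DAF replicate 1.

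**Figure D5:**
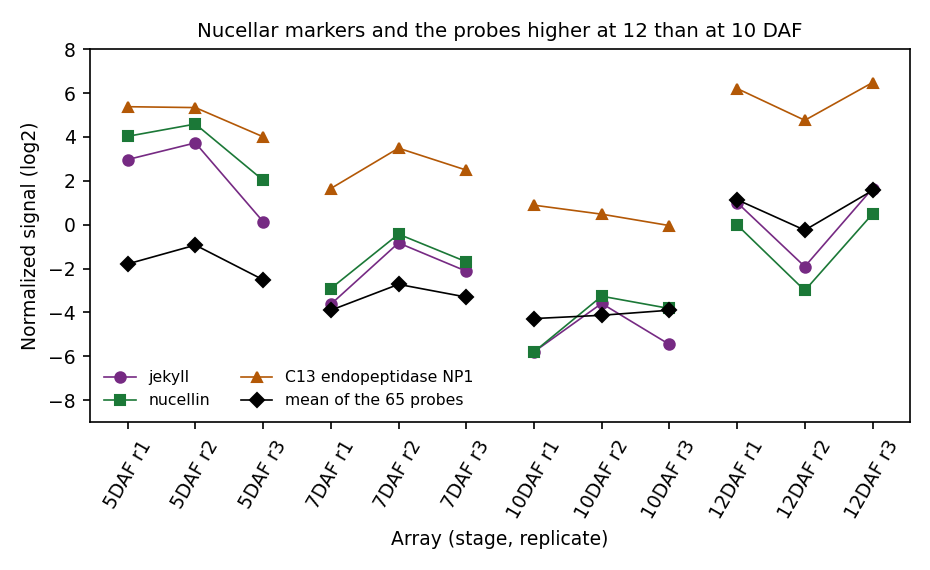
Normalized log2 signal per array of the nucellar genes jekyll and nucellin, of the C13 endopeptidase NP1 and of the mean of the 65 probes higher at 12 than at 10 DAF. Arrays are ordered by stage and lines join the arrays of a stage. Among the 12 DAF arrays replicate 2 was lowest for jekyll (-1.91, against 1.01 and 1.65) and for the mean of the 65 probes (-0.25, against 1.14 and 1.56).

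Over the whole span from 5 to 12 DAF, hordoindoline-B1 (BG367535) rose 169-fold from -3.0 ± 0.18 to 4.40 ± 0.14 (SD, n = 3; limma adjusted p = 3e-08), hordoindoline-a (TA32310_4513), well above background on 1 of 3 arrays at 5 DAF, 475-fold and the amylase/trypsin inhibitor CMd (TA30929_4513) 40.6-fold. The fold of hordoindoline-a was 179 without 5 DAF replicate 3 and 784 and 766 without replicates 1 and 2, and its log2 value was 6.53 with normexp. Of 18 storage protein genes, 15 rose and 2 fell, the same numbers when adjusted over the list alone (median log2 fold change 4.44; camera adjusted p = 8.34e-06; adjusted p = 0.0858 with an estimated correlation). As for the step from 5 to 7 DAF, RNA of neighbouring tissue was not told apart from expression in the transfer cells. Of 133 histone genes, 96 fell and 4 rose. When adjusted over the list alone, 99 fell and 5 rose (median log2 fold change -2.08; camera adjusted p = 1.26e-16; adjusted p = 0.693 with an estimated correlation), with histone H2A.1 (TA30084_4513) 22.2-fold and protein H2A.6 (TC191293) 30.8-fold lower. Of 83 genes of cytosolic ribosomal proteins, 55 fell and 3 rose. When adjusted over the list alone, 59 fell and 3 rose (camera adjusted p = 4.43e-09; adjusted p = 0.714 with an estimated correlation), with the 40S protein S15a-1 (BQ658135), well above background on 1 of 3 arrays at 12 DAF, 14.2-fold and ribosomal protein S10 (TA28334_4513) 4.62-fold lower.

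Cell cycle and DNA replication genes fell in 15 of 41 cases and rose in 2, the same numbers when adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.0858 with an estimated correlation). Cyclin-D6-1 (TA49348_4513) was at least 6.64-fold and replication protein A (TA42117_4513), which binds single-stranded DNA, at least 17.9-fold lower, bounds not reached with normexp (log2 fold changes of -2.42 and -3.19) or, for the latter, with the deposited values (-4.01). Photosynthesis genes rose in 14 of 18 cases and fell in none, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.003; adjusted p = 0.496 with an estimated correlation), with Lhcp2.3 (TA47820_4513) 29.9-fold and LHC Ib-20 with a log2 fold change of 3.39 ± 0.37 (SE). Of 45 heat shock and chaperone genes, 21 rose and 5 fell, and 23 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0078; adjusted p = 0.651 with an estimated correlation). As between 7 and 10 DAF, sample quality was not told apart from stage as the source of this rise. A small heat shock protein (TA32595_4513) rose 193-fold and heat shock protein 80 (AJ434772) 85.5-fold. Of 85 transcription factor genes, 33 rose and 10 fell, and 37 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.693 with an estimated correlation). A MADS-box factor, WM32A (TA53207_4513), well above background on 1 of 3 arrays at 5 DAF, rose 84.7-fold (log2 fold change 6.4, and 4.01 with normexp) and WRKY factor 66 (BQ767303) 42.5-fold. Of 19 abscisic acid genes, 10 rose and none fell, and 11 rose when adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.693 with an estimated correlation), including an ABA-responsive protein (LOC548112), 36.1-fold, and PHV A1 (TA32029_4513), 37.6-fold, which was well above background on 1 of 3 arrays at 5 DAF. Lipid transfer proteins, defensins and thionins rose in 8 of 18 cases and fell in 1, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0341; adjusted p = 0.714 with an estimated correlation), and this list call was lost without 5 DAF replicate 1 (adjusted p = 0.17) or replicate 3 (adjusted p = 0.092) and with every pattern match kept (adjusted p = 0.32). Under median scaling, which moved the median of all probes by -0.84, the median log2 fold changes of the heat shock and transcription factor lists turned negative, while their tests stayed upward (camera adjusted p = 0.00011 and 0.011).

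Large single increases included class III peroxidase 135 (TA36365_4513), at least 427-fold, a pathogenesis-related protein 1.2 (TA32324_4513), at least 134-fold, and a copper amine oxidase (TA45590_4513), at least 135-fold, since none was well above background on any 5 DAF array. Without 5 DAF replicate 3, which had the lowest detection limit of its stage, these bounds were 262, 82.3 and 82.8, and that of the peroxidase was 854 and 278 without 12 DAF replicates 2 and 3. With normexp their log2 fold changes were 7.82, 5.92 and 5.76, each less than the bound printed, and with the deposited values 8.19, 6.49 and 6.21, also less. A metallothionein-like protein (TA32551_4513), of a metal-binding family, rose 390-fold, and the transcript described as FliL (TA34846_4513), well above background on 2 of 3 arrays at 5 DAF, 951-fold (593 and 1630 without 5 DAF replicates 2 and 3). Formate dehydrogenase (TA31856_4513) was at least 45.4-fold lower, a transcript described as the pilus protein PilN (TA47663_4513) at least 37.4-fold, a transcript described as a pollen allergen (TA47935_4513) at least 26.3-fold, a microtubule-associated protein (TA47052_4513) at least 15.8-fold and a reticulon-like protein (TA44342_4513) at least 11.8-fold. With normexp the log2 fold changes of these 5 were -5.06, -5.2, -4.34, -3.46 and -3.28, each less in size than its bound. Beta-D-xylosidase (TA55556_4513), a wall hydrolase, fell 48.8-fold from 5.42 ± 0.11 to -0.19 ± 0.10 (SD, n = 3).

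In all, 8386 probes differed between 12 and 5 DAF, 4484 higher and 3902 lower at 12 DAF, without overlap of the 3 values of each stage for 54.4% of tested probes (chance, 10%). The count was 9255 with scan date as a block and 6995 with slide as a random block. The higher share of these calls was 20.9% under median scaling against 53.5%.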

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

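The scan date block, median scaling, the deposited value table and the run with every pattern match kept were added for the gene lists after the data were seen. The count of probes changed between 7 and 5 DAF (6763) stayed within 1.5 times except without 7 DAF replicate 1 (4447). It was 4447 to 7211 over single arrays left out and up to 8394, with array weights. The count for 10 against 7 DAF (4307) was 1389 without a filter on dim probes, 1758 with slide as a random block and 6989 with array weights. Over single arrays left out it was 1722 to 7053, and outside 1.5 times without 7 DAF replicate 1 (1722), 2 (2623) or 3 (2075), 10 DAF replicate 2 (2398) or 5 DAF replicate 3 (7053). The count for 12 against 10 DAF (65) was 19 with normexp, 21 without a filter, 8 with the stricter filter (13502 probes tested), 13 with slide as a random block, 108 with a variance trend and robust fitting, 633 with array weights and 19 in a fit of these 2 stages alone. Over single arrays left out it was 7 to 330: without 12 DAF replicate 1 (7), 2 (330) or 3 (11), 10 DAF replicate 1 (19), 2 (28) or 3 (263), 7 DAF replicate 2 (30) or 3 (26), and 5 DAF replicate 1 (31) or 3 (106). For 12 against 5 DAF (8386) only the run without a filter lay outside, with 22889 of 42650 probes. Arrays left out gave 6392 to 9471. The F test (10692) gave 18056 without a filter and 8472 to 12027 over arrays left out. List calls (26) numbered 0 with an estimated correlation, 45 with fry, which ended 4 of the 26, and 22 to 31 over arrays left out. With scan date as a block 28 lists passed, and all 26 calls held, as they did with slide as a random block. The cause of these shifts was not tested.

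The array weights gave 12 DAF replicate 1 a weight of 15.8 against 0.108 to 2.09 for the others, so that setting rests largely on 1 array. A first run of the weights by restricted maximum likelihood on probes with complete values had not converged (weight of 296 for that array; 10742, 7886, 1466 and 15333 probes in the 4 comparisons and 17293 by F test), and the default method on all tested probes was taken in its place after these counts were seen. Median scaling moved the median of all probes by -0.91, 0.70, -0.63 and -0.84 (log2) in the 4 comparisons, and its shares of higher calls were 15.8%, 90.1%, 92.9% and 20.9% against 54.1%, 59.7%, 100% and 53.5%. Quantile normalization moved it by -0.15 for 10 against 7 DAF and -0.18 for 12 against 5 DAF, and gave 50 probes higher and 23 lower for 12 against 10 DAF. The higher share was 71.6% for 10 against 7 DAF with the stricter filter and 83.9% for 12 against 5 DAF with no filter. The replicate block gave 7026, 4634, 49 and 8535 probes, 11015 by F test and 28 lists. Of 18 same-number pairs, 6 had deviations correlated over 0.1 across probes, and 6 of 12 arrays had their best partner in another stage under their own number. These 6 pairs were those of replicate 1 (r = 0.432, 0.346 and 0.29) and of replicate 3 (0.232, 0.24 and 0.211) among 5, 7 and 10 DAF. The other same-number pairs lay from -0.182 to 0.091, and pairs of different number reached 0.237. A source shared by arrays of the same number at 5, 7 and 10 DAF therefore stays open, and the main fit has no term for it. Of 88 named results past the test, 73 stayed past it under all alternatives, 15 lost it under at least 1 and 0 reversed. A histone H2B.1 (BI953670), not past the test for 12 against 10 DAF, went from -0.98 to 0.15 (log2) with normexp. Signal over background limited the 12 DAF stage most, with 78.5% to 83.2% of tested probes well above it per array.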

Other observations

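Of the tests of explanations in this part, the splits of the samples were planned, and all others were chosen after the result was seen. Aleurone markers had a median stage profile that went from -1.25 at 5 DAF to 0.89 at 12 DAF (9 genes), with 5 higher and 1 lower between these stages (6 and 1 adjusted over the list alone), and the list did not pass (limma camera, adjusted p = 0.256). The size of this rise depended on the processing. The median log2 fold change was 2.134, but 1.439 with quantile normalization, 1.127 with normexp, 1.045 under median scaling and 0.558 with the deposited values. Trehalose and SnRK1 genes, of sugar signalling, had 5 of 7 higher and 1 lower over the span, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.133). Of 23 metal and ion transport genes 9 rose and 5 fell (camera adjusted p = 0.345). Of 112 ubiquitin and proteasome genes 37 rose and 18 fell (camera adjusted p = 0.419). Of 43 amino acid synthesis genes 8 rose and 13 fell (camera adjusted p = 0.478), where the median log2 fold change was -0.282 and the mean 0.022. Adjusted over the list alone these were 10 and 5, 37 and 18, and 8 and 13. Under median scaling the median of the ubiquitin list turned to -0.537.

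Other lists did not pass over 5 to 12 DAF, with these camera adjusted p-values: nucellar markers 0.835 (median log2 fold change 0.114, mean -0.225), vascular and xylem markers 0.554, two-component signalling and cytokinin 0.378, ethylene 0.317, auxin 0.888 and gibberellin 0.234. The adjusted p was 0.872 for sugar transport and cleavage, 0.449 for amino acid and peptide transport, 0.902 for proton pumps, 0.687 for cell wall synthesis, 0.687 for the cytoskeleton, 0.414 for mitochondrial energy metabolism, 0.902 for glycolysis and fermentation, 0.562 for lipid metabolism and 0.687 for vesicle trafficking. None of these was called in the other 3 comparisons. Starch synthesis, called between 5 and 7 DAF (adjusted p = 0.555 with an estimated correlation), had 0.379 over the span.

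The real split of the arrays gave 6763, 4307, 65 and 8386 probes in the 4 pairwise comparisons, and the highest of the other 9 of 10 splits gave 1, 3, 0 and 0, but 10 splits are too few for a share under 0.05. For the F test, 1 of 100 splits, the real one, reached 10692 probes and the highest other gave 4192. This argues against a random grouping of the arrays as the source of that count. Since each slide holds 1 stage, it does not tell stage from slide.

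The 65 probes higher at 12 than at 10 DAF varied between replicates of a stage, and 12 DAF replicate 2 was lowest in 54 of them. Higher local background on the 12 DAF arrays is argued against as the whole of their rise, since their median log2 fold change was 3.28 after normexp correction (lower quartile 2.25), against 4.78 (3.93) before it. These probes were chosen for their rise on the same arrays, and the count of calls fell from 65 to 19. A part played by background therefore stays open. A candidate explanation is RNA of nucellar cells collected with the transfer cells: over the 12 arrays the mean deviation of the 65 probes from the stage mean correlated with that of 8 nucellar markers at r = 0.802 (exact one-sided permutation within stages, p = 0.0069; rho = 0.671, p = 0.0069; r = 0.712 without the 2 farthest arrays), adjusted p = 0.058 over 34 lists, of which proteases (0.944) and cell wall modification (0.826) lay higher. The nucellar and protease lists share probes. Jekyll and nucellin carried it (r = 0.90 and 0.92), the legumain leg-3 had 0.50 and the 5 others -0.49 to 0.08, and 0 of the 8 passed the test between 10 and 12 DAF, with 3 higher and 1 lower when adjusted over the list alone (list camera adjusted p = 0.608; list median -0.193, mean 0.928). Jekyll went from -4.95 ± 1.19 to 0.25 ± 1.89 (SD, n = 3) between these stages, a log2 fold change of 5.2 with a wide spread (limma adjusted p = 0.10). The C13 endopeptidase NP1, 1 of the 65 and not among the 8 markers, was lowest at 10 DAF (0.89, 0.48 and -0.04). It lay at 4.01 to 5.38 at 5 DAF and 4.76 to 6.48 at 12 DAF. Jekyll and nucellin were also lowest at 10 DAF. NP1 had its lowest replicate in common with both at 5, 7 and 12 DAF, but not at 10 DAF. Nucellar RNA and a change in the transfer cells that differed between samples therefore both stay open. Of the 65 probes, 19 (29.2%, against 0.967% of all tested probes) varied within stages with the mean of jekyll and nucellin at r over 0.8, a pair chosen after its values were seen, and 29 were also higher at 5 than at 7 DAF, as the pair of markers was, while 5 were lower. Among all 19138 tested probes, 3104 were higher and 3659 lower at 5 than at 7 DAF.

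10 DAF replicate 3 correlated more with the 12 DAF arrays (mean r = 0.967 across probes) than with the other 10 DAF arrays (0.946). An exchange of labels with a 12 DAF array is argued against, since each such exchange called 0 probes against 65 and 0 of the 12 DAF arrays were closer to 10 DAF, although 12 DAF replicate 2 lay 0.59 of the way toward 10 DAF over the probes called without it. Cells of a later stage than labelled stay open as an explanation. Over 263 probes called without replicate 3, its median position was 0.81 of the way to 12 DAF. Replicates 1 and 2, left out in turn, lay at 0.01 and 0.07 over their own smaller sets of 19 and 28 probes. These positions cannot decide the question. Only 65 probes were called with replicate 3 included, so the set of 263 favours probes on which it lies toward 12 DAF. The 330 probes behind the position of 12 DAF replicate 2 carry the same limit. The sets of 19 and 28 were called with replicate 3 among the 10 DAF arrays, which favours probes on which it differs from 12 DAF. The positions of replicates 1 and 2 therefore cannot be set against that of replicate 3. 10 DAF replicate 2 also correlated about as much with the 12 DAF arrays (0.953) as with its own stage (0.954). Slide cannot be told apart: in 0 of 3 stages did the pair on 1 slide correlate most, but by gaps as small as 0.953 against 0.955 at 10 DAF, and the consensus correlation within slides was 0.442. The wrong stage of a sample and a real spread of grain development within a harvest were not told apart by these values.

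Photosynthesis genes, fixed as markers of the green pericarp, were higher at 10 than at 7 DAF in 11 of 18 cases. Scan date is argued against, since with it as a block the list stayed higher (adjusted p = 0.032 at the preset correlation; median log2 fold change 1.79), although the list call itself is lost without the block at another setting (adjusted p = 0.59 with an estimated correlation). Pericarp RNA cannot be told apart from expression in the transfer cells: 0 of 9 readings of 3 Rubisco small chain and activase probes at 10 DAF were well above background, which would argue against it, but only 2 of 36 readings on any array were, so that nothing shows that these probes respond. Both may contribute.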
